A study of Homo sapiens with 2 samples.

How the data were processed

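Promoter-capture Hi-C was measured in K562 cells, an established human chronic myelogenous leukaemia line, after 24 h with the vehicle DMSO or with 100 nM ponatinib, an inhibitor of the ABL kinase. There was 1 library per treatment, made from the same number of harvested cells, per the labels' protocols. Crosslinked chromatin was cut with HindIII, the ends were marked with biotin and ligated, and RNA probes pulled promoter fragments out of the resulting Hi-C library, per the labels' protocols.

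The authors deposited 1 list of interactions per library. Each line gives a captured (bait) fragment, its partner fragment and a score, which is the authors' own value for that interaction, and no score lies below 5. The genome build is hg38, per the submitters' processing notes. The aligner, the interaction caller, the definition of the score and the threshold behind the lists are not given in the sources used here. The files hold no read counts, so the depth of each library is unknown and no value was corrected for it. Scores were not normalised between the libraries here. They were used to describe, rank and filter interactions within a list, and the comparison of scores across shared interactions describes the lists, not the strength of contacts.

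An interaction was taken as an unordered pair of fragments. The ponatinib list had 91306 lines and 91305 interactions, since 1 pair was listed in both orientations. Interactions were called shared when the identical pair of fragments was in both lists. Distance was taken between fragment midpoints. A promoter-to-promoter interaction had bait fragments at both ends.

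Genes came from a RefSeq table of assembly GRCh38.p14, the same build as the lists, with 20037 protein-coding genes. The plan was to place genes by their transcription start, but the table gives no strand. A gene was therefore assigned to each listed bait fragment that holds either of its ends, so a fragment at the 3' end of a gene can be counted. By this rule 13721 genes had a listed bait fragment, 12050 of them 1 fragment only. When gene positions were shifted by 1 Mb, 2811 genes did. Genes with the same set of fragments have the same number by construction, and genes that share only some fragments have those interactions in common. Sharing is named below for some genes only. Fragments of KLF1, CISH, CDK2, CDKN1B, LDHA, BCL2L11, RPS27, RPL7, GFAP and C1orf232 also hold ends of other genes. A gene with no listed bait fragment was not analysed here.

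For each gene the interactions of its fragments were counted per library, and the log2 ratio was taken as log2((ponatinib + 1)/(DMSO + 1)), which understates the difference of genes with few interactions. A gene was called different by number when it had at least 5 interactions over both libraries and a ratio of at least 2-fold. With 1 library per group no test of the treatment exists. Intervals are 95% intervals, exact binomial (Clopper-Pearson) for shares and for ratios of numbers, from order statistics for medians, Newcombe's for differences of shares, and Fisher's z for rank correlations. They cover counting error only and treat interactions as independent, which neighbouring fragments are not.

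The 19 gene lists (640 members), most comparisons of the report and most alternatives were fixed before the data were examined. Most tests of the closing section were chosen later. The lists covered erythroid, megakaryocyte, granulocyte and monocyte genes, stem and progenitor genes, the STAT5 and JAK, ERK, and PI3K, AKT and mTOR pathways, cell cycle, BCL2 family and cell death, glycolysis and hypoxia, cholesterol and fatty acid synthesis, lysosome and autophagy, interferon response, resistance to tyrosine kinase inhibitors (TKI) and drug transport, ribosomal proteins, chromatin architecture and histones. Lymphoid markers and liver and neuron markers stood for other cell types. The median log2 ratio of each list was set against 10000 random lists of the same size, matched on the number of interactions over both libraries.

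Genes were named by a rule fixed beforehand. It took a set of globin, erythroid and BCR-ABL1 pathway genes always, up to 2 members with the largest gain and 2 with the largest loss in each list described, the 10 genes with the largest gain and the 10 with the largest loss in number, and the genes at the 5 highest scoring interactions of each kind. Not every gene the rule allows is named, and some are not reported here.

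The alternatives were a score of at least 7 or at least 10, lists of equal length made of the highest scores, and pairs on 1 chromosome only. Ends were also matched within 5 or 10 kb. For numbers per gene they were a pseudocount of 0.5, ponatinib numbers divided by the ratio of list lengths, and a minimum of 10 interactions. Others were gene ends within 1 kb of a fragment, and means of lists in place of medians. Genes on 1 fragment only, lists without chromosomes 9, 13 and 22, and gene lists without their most different member were added after seeing the data. The steps were tested on simulated data. Among 13721 genes, 200 with a mean of at least 10 interactions over the libraries were changed 4-fold, and 199 were recovered as different. The median gene had 4 interactions in each list, so recovery at most genes and of smaller changes was not tested. Of lists of genes shifted 2-fold 40 of 40, and of lists of unshifted genes 2 of 40, lay outside the range of random lists. Smaller shifts of lists were not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.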

Results

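Promoter contacts were mapped by promoter-capture Hi-C, which pulls ligated fragment pairs with a promoter at 1 end out of a Hi-C library, in K562 cells. K562 is an erythroleukaemic cell line that carries the BCR-ABL1 fusion. The cells had received DMSO or 100 nM ponatinib, a BCR-ABL1 inhibitor, for 24 h, and the comparison asks which promoter interactions differ after kinase inhibition. The DMSO list held 84049 interactions of 15835 bait fragments, and the ponatinib list 91305 interactions of 15938. There were no replicates, so no difference reported here has a replicate check and no test of the treatment was possible. Read depth is unknown, and intervals cover counting error only. Each score is the authors' own value for an interaction within its list.

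The highest scoring shared interactions joined distant regions or different chromosomes, among them a region of chromosome 9 near ABL1. The top-ranked shared pair joined a fragment in XKR3 on chromosome 22 (16807977 to 16818639) to a fragment in NUP214, a nuclear pore gene distal of ABL1 on chromosome 9 (131190202 to 131199007). Its score was 1682.28 in DMSO and 1874 in ponatinib, and its chromosome 22 end lies more than 1 Mb from BCR (23180509 to 23318037). A fragment in GPC6 and the NALF1 promoter fragment, 14495 kb apart on chromosome 13, scored 505.61 in DMSO and 707.79 in ponatinib. A fragment in GRID1 on chromosome 10 and one in CDC25A, a cell cycle phosphatase gene on chromosome 3, scored 441.22 and 514.17. Interactions between chromosomes 9 and 22 numbered 1654 in DMSO and 1781 in ponatinib. Their ratio was 1.08, with a 95% interval (1.01 to 1.15) that holds the 1.09 of the whole lists. These interactions made up 26.9% of all interactions between chromosomes in DMSO (25.8 to 28.0%) and 27.0% in ponatinib (25.9 to 28.1%). Of these, 1636 and 1765 had their chromosome 9 end within 1 Mb of ABL1, and 1116 and 1212 had their chromosome 22 end within 1 Mb of BCR. BCR itself had no listed bait fragment.

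NUP214, on the rearranged part of chromosome 9, had more interactions than any other gene in both lists. It had 667 in DMSO and 807 in ponatinib, with 479 shared; among pairs on 1 chromosome 51.1% of its interactions were in ponatinib (42.5 to 59.6%). ABL1 had 217 and 256. Of its bait fragments, the one at 130701356 to 130714364 had 11 and 19, and the one at 130886468 to 130895045, which also holds an end of QRFP, had 206 and 238. LAMC3, a laminin gene, had 132 and 159, and its neighbour AIF1L had 121 and 152. On chromosome 13 the fragment shared by NALF1 and LOC124903206 had 468 and 547, and at scores of at least 7 the share in ponatinib was 50.3% (47.1 to 53.6%). The strongest interactions found in 1 list only also lay here. In DMSO the top one joined a RAB36 fragment next to BCR (22, 23144401 to 23152974) to a fragment in ABL1 (130851267 to 130854620) with a score of 234.74. In ponatinib the top one joined the same RAB36 fragment to another ABL1 fragment (130739459 to 130742346) with a score of 342.64.

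MYC, a transcription factor gene downstream of BCR-ABL1 signalling, had 34 interactions in DMSO and 52 in ponatinib, of which 30 were shared. The bait fragment was 127733745 to 127744733 on chromosome 8. The ratio was 1.53, with an interval of 0.974 to 2.43 that holds 1. Most partners lay far downstream. Beyond 1 Mb there were 24 in DMSO and 39 in ponatinib, with 23 shared, at 129508754 to 129734576 and so 1771 to 1991 kb from the promoter fragment. Partner fragments that overlap CCDC26, a long non-coding RNA gene in that region, numbered 13 in DMSO and 27 in ponatinib, with 13 shared. Further downstream than CCDC26 there were 11 and 12, with 10 shared. Within 1 Mb of the MYC fragment the numbers were 9 and 11, and the partners in PVT1, a non-coding gene next to MYC, were 5 in each list and all shared. CCDC26 and PVT1 were chosen after their values were seen. Among the shared partners beyond 1 Mb the median score was 10.7 within the DMSO list and 18.2 within the ponatinib list. Of all 30 shared partners 21 had the higher score in ponatinib, and 19 of these 21 lay beyond 1 Mb. Most shared partners within 1 Mb had the lower score there.

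**Figure D1:**
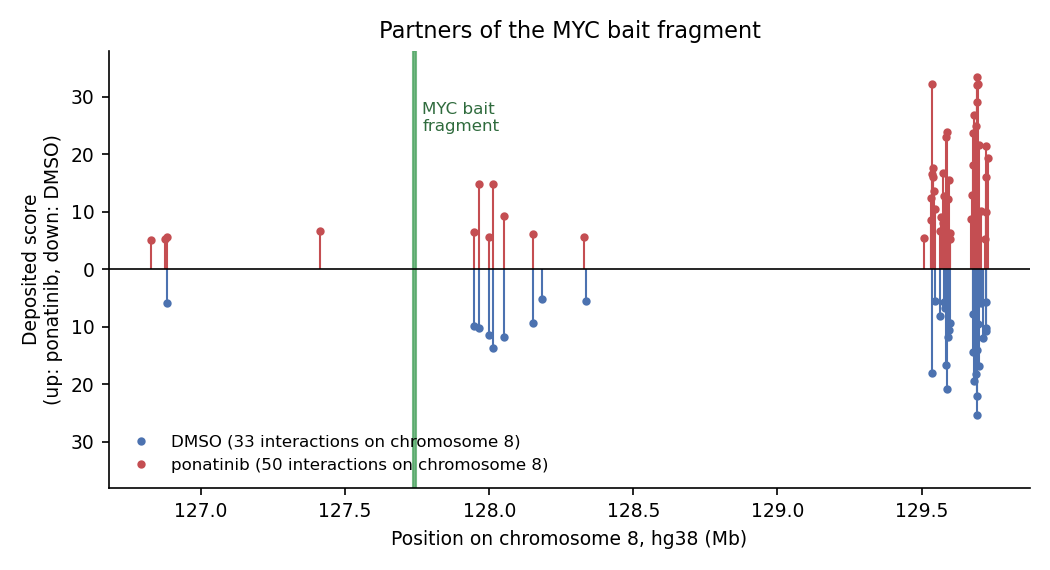
Partners of the MYC bait fragment on chromosome 8, with position in Mb (hg38) on the horizontal axis and the deposited score on the vertical axis, ponatinib upwards and DMSO downwards. Each point is 1 interaction; most lie between 129508754 and 129734576, with 24 in DMSO and 39 in ponatinib beyond 1 Mb.

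At the beta-globin cluster on chromosome 11, bait fragments held HBB, HBD and HBG1. Together they had 12 interactions in DMSO and 15 in ponatinib, with 4 shared, a ratio of 1.25 (0.546 to 2.92). HBG1, a fetal globin gene that K562 cells express, had 5 and 5. HBB, the adult gene, had 2 and 1. Fragments at 5279020 to 5292119, within 25 kb beyond HBE1 where the locus control region lies, were contacted 3 times in DMSO and 6 times in ponatinib; this region was chosen after its values were seen. There, HBB had 1 and 0, HBD had 2 and 4, and HBG1 had 0 and 2. HBG1 and HBG2 are nearly identical in sequence, so reads of the HBG1 fragment are uncertain. At the alpha-globin cluster, HBZ had 1 and 0. HBE1, HBG2, HBA1 and HBA2 had no listed bait fragment. Of the erythroid transcription factor genes, TAL1 had 7 and 11, KLF1 had 2 and 2 and GATA1 had 1 and 5. At scores of at least 7 GATA1 kept 1 interaction, in DMSO, too few for a direction. At scores of at least 7 the beta-globin fragments had 1 interaction in DMSO and 8 in ponatinib, a ratio of 8 (1.07 to 355), and at 10 they had 0 and 0.

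Away from the rearranged chromosomes, the largest gain in number was at CCNB1, the mitotic cyclin B1 gene, with 7 interactions in DMSO and 42 in ponatinib. Both of its fragments had more in ponatinib, 3 and 14 at 69159346 to 69169607 on chromosome 5 and 4 and 29 at 69177723 to 69190157, which also holds an end of CENPH. WSB1, a ubiquitin ligase subunit gene, had 45 and 79. MAML2, a Notch coactivator gene, had 12 and 39, and C1orf232 had 44 and 71. Among the largest losses were TNFAIP8 with 30 and 9 and ATXN1 with 103 and 84, of which 42 and 38 were between chromosomes. EPC2 had 50 and 32, the histone gene H4C8 had 50 and 33, USP6NL had 26 and 10, and MINDY2 had 23 and 7. ELAPOR2 had 65 and 50, the fragment of LETM2 and NSD3 had 55 and 40, and RPS26 had 45 and 30. Taken as shares of a gene's interactions over both lists, 85.7% of those of CCNB1 were in ponatinib (72.8 to 94.1%) and 23.1% of those of TNFAIP8 (11.1 to 39.3%). The intervals of ATXN1 (37.7 to 52.3%), EPC2, H4C8, ELAPOR2, LETM2 and RPS26 hold 50%. At scores of at least 7 the shares were 78.9% (54.4 to 93.9%) for CCNB1 and 40% (12.2 to 73.8%) for TNFAIP8, and at 10 they were 80% (28.4 to 99.5%) and 50% (6.76 to 93.2%).

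Of 9787 genes with at least 5 interactions over both lists, 971 (9.92%) had at least 2-fold more in ponatinib and 613 (6.26%) at least 2-fold fewer. The median log2 ratio was 0.08. With each ponatinib number divided by the ratio of the list lengths the counts were 671 and 626. In lists of equal length they were 722 and 827, which turns the excess of genes with more, and at scores of at least 10 they were 216 and 60.

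**Figure D2:**
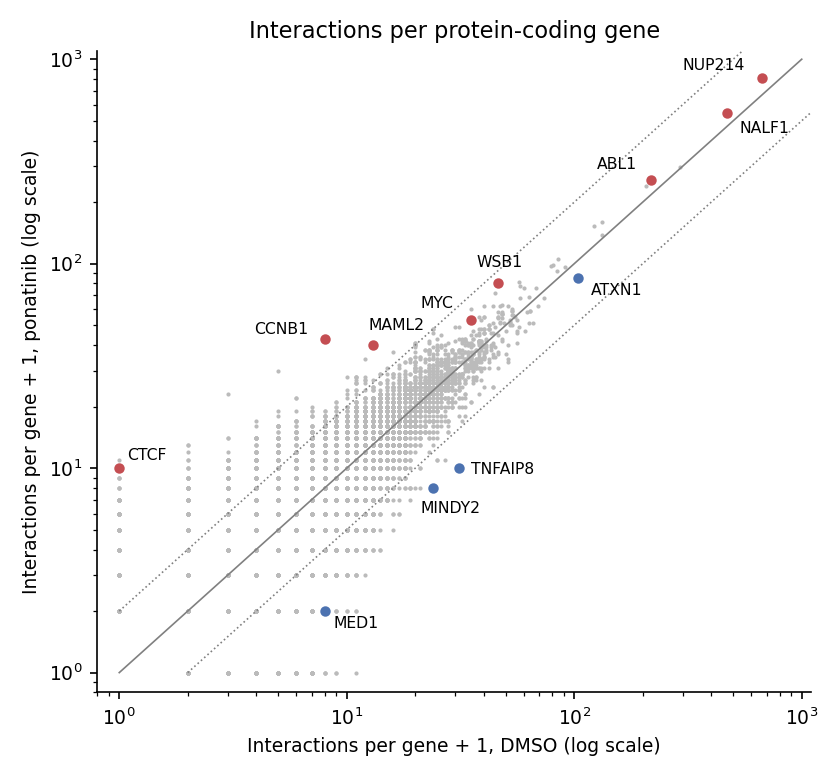
Interactions plus 1 of each protein-coding gene in DMSO (horizontal, log scale) and ponatinib (vertical, log scale), with 1 point per gene, a solid line at equal numbers and dotted lines at 2-fold. Red points are named genes with more interactions in ponatinib and blue points those with fewer; CCNB1 had 7 and 42, and TNFAIP8 had 30 and 9.

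Genes of cell cycle and replication had 315 interactions in DMSO and 408 in ponatinib, a ratio of 1.30 (1.12 to 1.51), and 21 of 37 measured members had more and 10 fewer. Next to CCNB1, CDK6, a G1 kinase gene, had 4 and 15. CDKN1B, the p27 inhibitor gene, had 22 and 18, and CDK2 had 16 and 13. The CDKN1B fragment at 12711792 to 12719042 had 12 in each list, and the one at 12721942 to 12727574 had 10 and 6. Without CCNB1 the list had 308 and 366. The median log2 ratio with CCNB1, 0.26, lay at percentile 89.2 of random lists. Ribosomal protein genes had 244 and 295, with 21 of 31 members more and 8 fewer, and were the only list whose median lay outside the central 95% of random lists (0.42, percentile 98.6). By the mean of the list the percentile was 84.4. In lists of equal length it was 99.3 and with gene ends within 1 kb of a fragment 99.65, both outside. No list lay outside at scores of at least 7 (ribosomal protein genes at percentile 93.3). With scores of at least 10 ribosomal protein genes lay inside (58.5), and the 2 lists outside were granulocyte and monocyte genes (percentile 0.570, 9 measured members) and cholesterol and fatty acid synthesis genes (percentile 97.6, 12 measured members). Of 40 simulated lists without a shift, 2 (5%) lay outside, so about 1 of 19 is expected by chance. RPS27 had 22 and 36, while RPL7 had 24 and 10 and RPL11 had 7 and 2. Genes of cholesterol and fatty acid synthesis had 151 and 200, at percentile 72.4. The ratio was 1.32, with an interval (1.07 to 1.65) that holds the 1.09 of the whole lists. Among these genes HMGCS1, an early enzyme of the cholesterol pathway, had 30 and 42. The fatty acid elongase gene ELOVL6 had 18 and 28, while IDI1 had 5 and 2. Glycolysis and hypoxia genes had 105 and 134 (percentile 74.4), with 15 and 25 at HIF1A, 10 and 19 at GAPDH and 11 and 9 at LDHA. Of the LDHA fragments, the one at 18386989 to 18400092 had 3 and 6 and the one at 18407027 to 18414324 had 8 and 3.

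Medians of lists of pathways downstream of BCR-ABL1 lay inside the range of random lists at all scores and at scores of at least 7 and 10. STAT5 and JAK pathway genes had 348 interactions in DMSO and 376 in ponatinib, a ratio of 1.08 (0.931 to 1.25) and a median at percentile 61.4, and without MYC they had 314 and 324. SOCS2, a STAT5 target and feedback inhibitor, had 46 and 51, PIM1, a kinase gene induced by STAT5, had 30 and 26, and CISH had 12 and 16. The order was turned at CISH when scores of at least 7 were required, with 45% of its interactions in ponatinib (23.1 to 68.5%), and at SOCS2 in lists of equal length, with 49.5% (38.8 to 60.1%). ERK pathway genes had 265 and 299 (percentile 72.8), with 5 and 10 at the ERK phosphatase gene DUSP5, 16 and 12 at SPRY4 and 9 and 5 at BRAF. PI3K, AKT and mTOR genes had 162 and 167 (percentile 79.8), with 5 and 10 at the lipid phosphatase gene INPP5D. The largest difference in this list was a loss, 14 and 6 at the fragment shared by SESN1 and CEP57L1. At scores of at least 7 its order was turned, with 57.1% in ponatinib (18.4 to 90.1%). BCL2 family and cell death genes had 225 and 241 (percentile 57.3), with 9 and 11 at BCL2L1, 15 and 20 at the proapoptotic gene BCL2L11 and 12 and 8 at BIRC3. Genes of TKI resistance and transport had 1049 and 1273 (percentile 29.5), and 382 and 466 without NUP214. Most of the latter were at ABL1, near NUP214 on chromosome 9, with 217 and 256.

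Medians of lineage lists lay inside the range of random lists at all scores, but at scores of at least 10 that of granulocyte and monocyte genes lay below it, with 33 interactions in DMSO and 27 in ponatinib. Erythroid genes had 330 interactions in DMSO and 380 in ponatinib, a ratio of 1.15 (0.991 to 1.34), with 21 of 42 members more and 13 fewer (percentile 50.7). CA1, a red cell carbonic anhydrase gene, had 12 and 23, and ALAD, a haem synthesis gene, had 5 and 14. RHAG had 61 and 57, with 56.8% in ponatinib at scores of at least 7 (44.7 to 68.2%). Megakaryocyte genes had 81 and 75, the only list with fewer in ponatinib, with 7 of 18 members more and 10 fewer (percentile 7.41). At scores of at least 7 the share of the list's interactions found in ponatinib was 55.8% (41.3 to 69.5%), against 48.1% (40.02 to 56.2%) at all scores and 46.4% (38.2 to 54.6%) in lists of equal length. The direction thus differs between settings, and each interval holds 50%. CD9 had 10 and 14, and LTBP1 had 17 and 14, with 57.1% in ponatinib at scores of at least 7 (28.9 to 82.3%). Granulocyte and monocyte genes had 113 and 125 (percentile 74.0), with 2 and 7 at the fragment shared by CSF1R and PDGFRB and 13 and 10 at FCGR2A. Stem and progenitor genes had 120 and 127 (percentile 82.3), with 6 and 13 at HOXB4 and 21 and 14 at MYB.

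Lymphoid markers, which stand for another cell type, had 133 and 165 (percentile 75.2), and liver and neuron markers had 76 and 110 (percentile 93.4). The ratio of the liver and neuron list was 1.45, with an interval (1.07 to 1.97) that holds the 1.09 of the whole lists. GFAP had 6 and 14, and APOB had 4 and 3. Without GFAP the liver and neuron list had 70 and 96, with 57.8% in ponatinib (49.9 to 65.4%), an interval that holds 50%. Chromatin architecture genes had 214 and 251 (percentile 31.0), and CTCF, the insulator protein gene, was listed at 0 in DMSO and had 9 in ponatinib. In the same list STAG1, a cohesin subunit gene, had 24 and 39. MED1, a Mediator subunit gene that shares a listed bait fragment with FBXL20, had 7 and 1. Its fragment at 39397580 to 39405334 on chromosome 17 had 5 and 1, and the one at 39448482 to 39452786 had 2 and 0. Histone genes had 989 and 1075 (percentile 67.7), lysosome and autophagy genes 110 and 123 (percentile 67.2), and interferon response genes 86 and 90 (percentile 34.3). At scores of at least 7 the smaller share of interactions was in ponatinib for granulocyte and monocyte (46.9%), glycolysis and hypoxia (48.4%) and interferon response genes (48.6%), and at 10 for granulocyte and monocyte genes (45%) and lymphoid markers (48.6%). In lists of equal length it was so for megakaryocyte (46.4%), PI3K, AKT and mTOR (48.2%), stem and progenitor (49.2%), interferon response (49.4%) and BCL2 family genes (49.7%). The intervals of all these shares hold 50%.

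**Figure D3:**
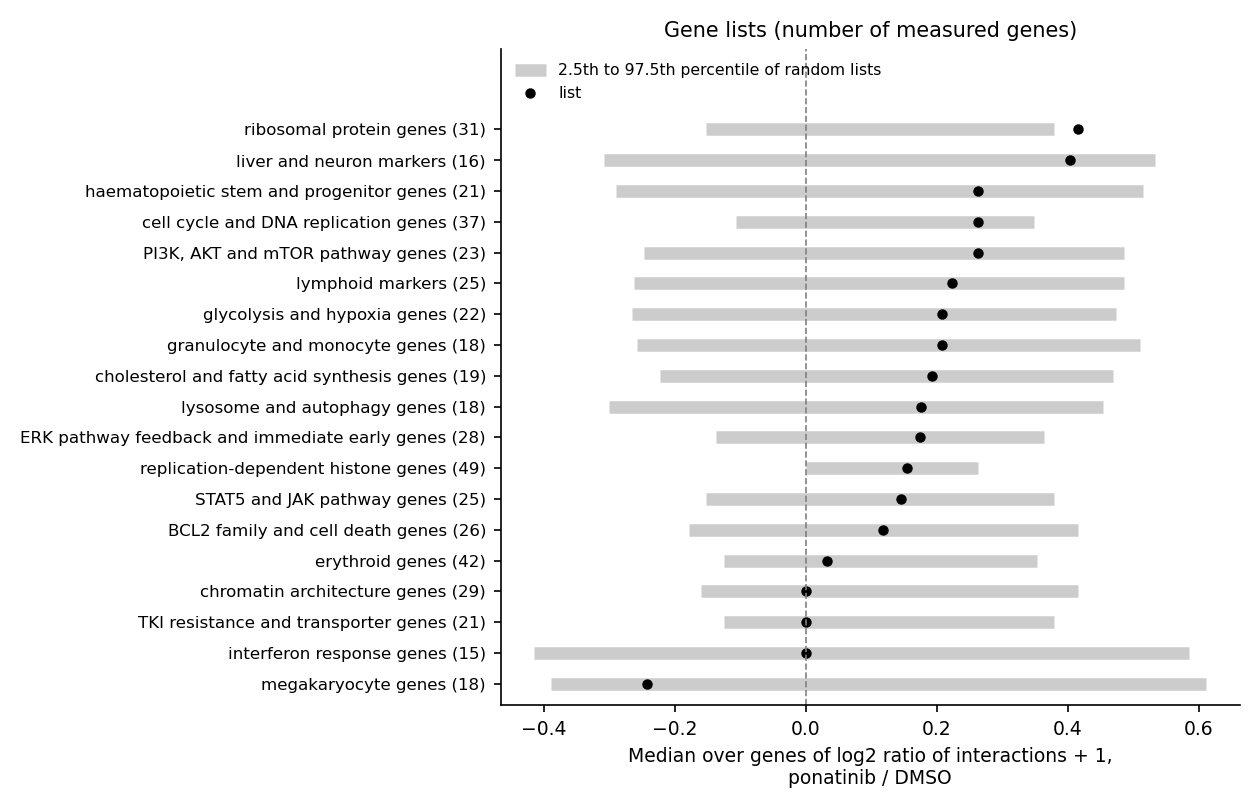
Median over the measured genes of each list of the log2 ratio of interactions plus 1, ponatinib over DMSO (points), with the central 95% range of 10000 random lists of the same size (grey bars). Ribosomal protein genes, at 0.42, are the 1 list outside its bar.

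The ponatinib list as a whole was longer by a ratio of 1.09 (1.08 to 1.10), and the ratio was above 1 on 23 of 23 chromosomes, from 1.03 to 1.17. It was higher at larger distances up to 5000 kb. Pairs under 20 kb apart had a ratio of 1.01 (0.965 to 1.06), those from 500 to 1000 kb 1.15 (1.12 to 1.18), those from 2000 to 5000 kb 1.31 (1.20 to 1.44), and those at 5000 kb or more 1.12 (1.01 to 1.23). Beyond 1 Mb the lists held 4108 and 5041 interactions, or 5.29% of same-chromosome pairs in DMSO (5.13 to 5.45%) and 5.97% in ponatinib (5.81 to 6.13%), a difference of 0.678 percentage points (0.453 to 0.902). The median distance was 234 kb (232 to 236) in DMSO and 242 kb (239.8 to 243) in ponatinib, a difference of 7.41 kb (4.84 to 9.98). Promoter-to-promoter pairs made up 19.1% (18.8 to 19.4%) and 18.7% (18.4 to 18.9%), a difference of -0.414 percentage points (-0.781 to -0.0476). It was -0.0286 (-0.404 to 0.347) in lists of equal length and -0.361 (-0.760 to 0.0367) without chromosomes 9, 13 and 22, where the interval holds 0 in both. Pairs between chromosomes made up 7.33% (7.15 to 7.51%) and 7.22% (7.06 to 7.39%). Their difference was -0.105 percentage points (-0.348 to 0.138), but 0.312 (0.0601 to 0.563) in lists of equal length and -0.344 (-0.528 to -0.161) without chromosomes 9, 13 and 22, so its direction depends on the setting.

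**Figure D4:**
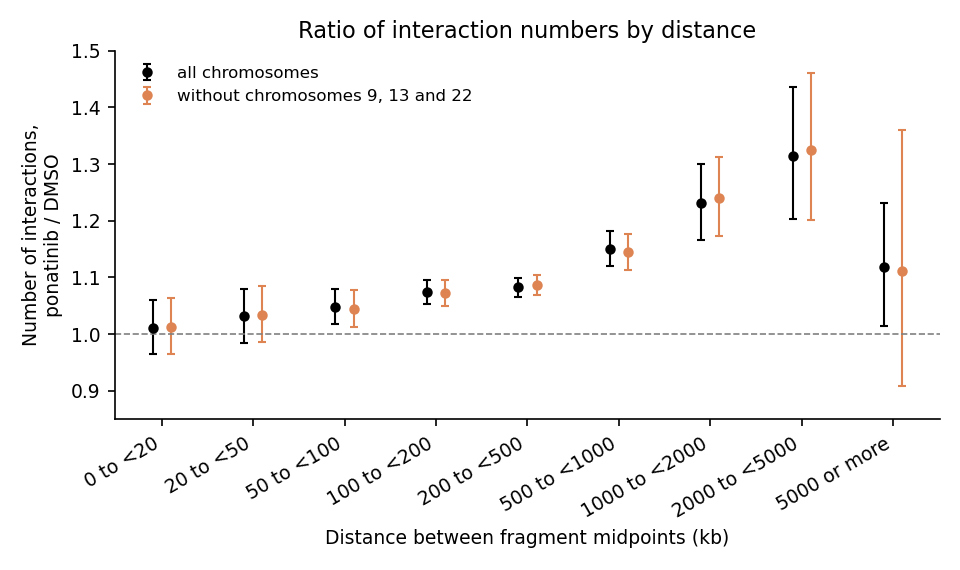
Number of interactions in ponatinib over that in DMSO (vertical) by distance between fragment midpoints in kb (horizontal), for all chromosomes (black) and without chromosomes 9, 13 and 22 (orange), with 95% counting intervals. The ratio was 1.01 under 20 kb and 1.31 from 2000 to 5000 kb.

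The identical fragment pair was in both lists for 37194 interactions, which is 44.3% of the DMSO list (43.9 to 44.6%), 40.7% of the ponatinib list (40.4 to 41.1%) and 26.9% of the union (26.7 to 27.2%). With both ends matched within 5 kb the share of the DMSO list was 67.5%. Of DMSO interactions scoring from 5 to under 6, 25.1% were in the ponatinib list (24.6 to 25.6%), and of those scoring 50 or more, 93.8% (91.7 to 95.6%). In the other direction the shares were 22.1% (21.6 to 22.5%) and 91.9% (89.8 to 93.7%). Shared pairs had a median distance of 184 kb, those in DMSO only 285 kb and those in ponatinib only 291 kb. Across shared interactions, which are not replicates, scores in the lists had a Spearman correlation of 0.573 (0.566 to 0.580), and 53.6% had the higher score in ponatinib (53.1 to 54.1%).

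**Figure D5:**
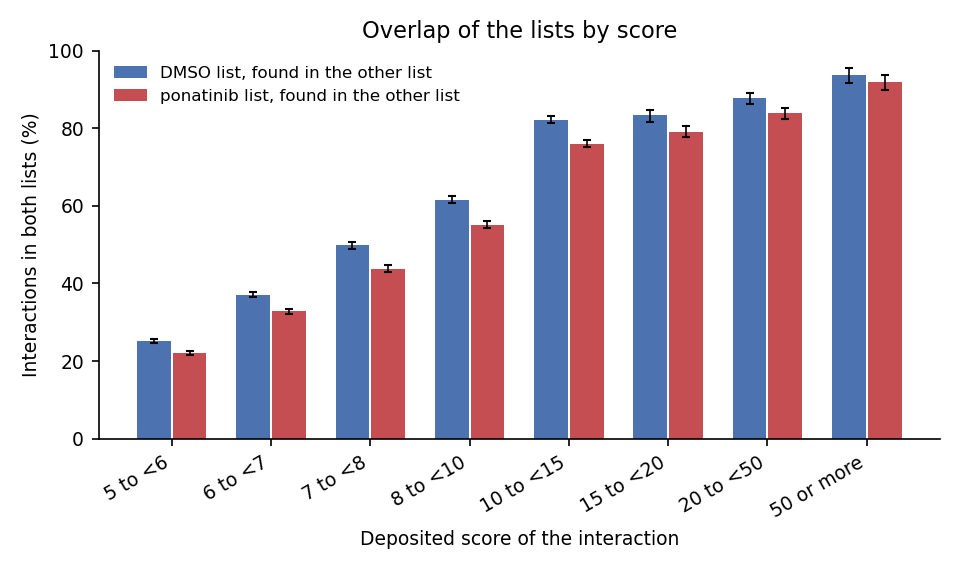
Share of the interactions of each list found in the other (vertical, %) by deposited score (horizontal), DMSO in blue and ponatinib in red, with exact 95% intervals. The share was 25.1% and 22.1% at scores from 5 to under 6, and 93.8% and 91.9% at 50 or more.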

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

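No paired analysis was possible because each group holds 1 library. Leaving out chromosomes 9, 13 and 22, genes on more than 1 fragment or a list's most different member was chosen after seeing the data. The ratio of list lengths was 1.14 at scores of at least 7 and 1.19 at 10. At these scores the share of DMSO interactions that were shared was 50.8% and 57.6%, the correlation of shared scores 0.590 and 0.707, the promoter-to-promoter difference -1.02 and -1.83 percentage points, genes with 2-fold more interactions 520 and 216 and with fewer 257 and 60, and lists outside the random range 0 and 2, ribosomal protein genes not among them. Fewer genes and calls enter by construction. The difference in median distance was 10.7 kb at 10. The beta-globin ratio was 8 (1.07 to 355) at 7 (1 and 8 interactions) and had no value at 10 (0 and 0). In lists of equal length the shared share was 42.7%, the promoter-to-promoter difference -0.0286 (-0.404 to 0.347) against -0.414 (-0.781 to -0.0476) in the full lists, and the ratio within 1 Mb reversed to 0.989, since equal lengths force a ratio near 1. On 1 chromosome the shared share was 45.4% and the correlation 0.525. The shared share was 67.5% within 5 kb, 72.3% within 10 kb and 84.0% for scores of at least 10 against the full list. With a minimum of 10 interactions 467 genes had more and 243 fewer, and by list means 0 lists were outside. Where no construction is named, the cause was not tested. Of 564 values of named genes under alternatives, 524 stayed within their counting interval and 26, at 18 genes, turned direction, none at the 13 genes whose interval left out equal numbers, though TNFAIP8 stood at 50% at scores of at least 10. Of 95 values of lists, 86 stayed within theirs. The alternatives reuse the same calls, and most named genes were picked for their differences in these lists. Genes with few interactions have wide intervals that most values stay inside. These counts therefore do not check the differences. Unknown read depth limits every comparison of numbers.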

Other observations

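The tests on the longer list, on neighbouring fragments and on chromosome pairs were chosen after the results were seen, the random split and the scores at genes with differing numbers before.

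Further chromosome pairs had interactions gathered in a narrow region in both libraries. Chromosomes 9 and 13 were joined by 1074 interactions in DMSO and 1319 in ponatinib, and chromosomes 13 and 22 by 257 and 368. Chromosomes 3 and 10, the pair that holds CDC25A and GRID1, had 94 and 102, chromosomes 6 and 16 had 59 and 69, chromosomes 1 and 18 had 54 and 52, and chromosomes 5 and 18 had 41 and 43. ATXN1, at the chromosome 6 end of such a pair, had 42 interactions between chromosomes in DMSO and 38 in ponatinib. For the 4 leading pairs, the lowest share of a pair's interactions inside 1 window of 10 by 10 Mb was 66.6% in either library, against a median of 6.90% over 35 other pairs. Rearranged chromosomes of the cell line may therefore account for this pattern, and the windows name candidate junctions for follow-up. No biological explanation tied to the treatment was tested for it.

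The ponatinib list was longer, and more so at larger distances. Unless the caller treats pairs between chromosomes differently, a larger share of random calls would add such pairs at least as fast as others. Apart from pairs that join chromosomes 9, 13 and 22 to each other, they numbered 3174 and 3127, a ratio of 0.985 (0.937 to 1.04). The caller is unknown, and the pairs counted include gathered ones such as those of chromosomes 3 and 10. More random calls therefore stay open. Without any interaction that touches chromosomes 9, 13 and 22 the ratio beyond 1 Mb was 1.25 (1.19 to 1.31) against 1.08 within 1 Mb, and in lists of equal length the share beyond 1 Mb still differed by 0.696 percentage points (0.467 to 0.926), which argues against these chromosomes alone and against weak calls of the longer list. Higher detection in the ponatinib library stays open, since 53.6% of shared interactions had the higher score there and all 23 chromosomes had a ratio above 1. A longer reach of promoter contacts after ponatinib may also give this pattern and stays open, untested with 1 library per group.

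Numbers of interactions of 1584 genes differed at least 2-fold. When the interactions found in 1 list only were assigned to the libraries at random, 1000 splits gave a median of 1183 and at most 1317 genes, but these splits treat interactions as independent and cover counting noise only. An excess over them was to be expected between single libraries, so the bound set beforehand, a count above every split, decides nothing and how much of the count is chance stays open. Detection that differs for a whole fragment also stays open: at genes with 2-fold more interactions 57.0% of the shared interactions had the higher score in ponatinib (54.1 to 59.8%), and at genes with 2-fold fewer 43.9% (39.9 to 47.9%). The mean centred log2 ratio of the neighbour in the direction of the change was 0.0170 (shuffled range -0.0447 to 0.0353) without common partners. With common partners it was 0.0304, above the shuffled range (-0.0365 to 0.0296) but below the highest shuffle (0.0562). These 1509 and 1991 fragments had themselves changed at least 2-fold. The mean of their neighbours lay inside the range without common partners and above it with them, so the test decides nothing. A change over a region cannot be told apart from a change of single fragments. The test planned first, a Spearman correlation over all neighbouring fragments, those without a 2-fold difference included, gave 0.00129 (shuffled range -0.0338 to 0.0358) without common partners and 0.0144 (shuffled range -0.0284 to 0.0280) with them. A treatment effect on single fragments such as those of CCNB1 may contribute and was not tested apart from detection.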
